A study of Mus musculus with 24 samples.

How the data were processed

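RNA was measured by messenger RNA sequencing in whole mouse embryos and in yolk sacs at embryonic day 9.5. Per the labels' protocols, the mice were of the C57BL/6 strain, RNA was taken with TRIzol, libraries were made with a KAPA mRNA HyperPrep kit and reads came from an Illumina NovaSeq instrument. The 24 libraries fell into 6 groups per tissue, given by line (a Setd2 null allele or a Setd2 catalytic dead allele, named CD) and genotype (wild type, WT; heterozygous, HE; homozygous, HO), with 2 libraries per group. Groups and replicate numbers were taken from the labels alone. The labels do not say that replicates were from separate animals or litters, so p-values measure only the spread between these samples. Replicates differed in sex transcripts in embryo null HO and CD HE and in yolk sac null HE, null HO and CD HE. These were not the same animal. Elsewhere, except by Gm8210 in yolk sac CD WT, spread may be technical.

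Reads were trimmed with fastp 0.22.0, aligned with HISAT2 2.2.1 to mm10 and counted per gene with featureCounts 2.0.1, per the submitters' processing notes, which also name DESeq2 1.32.0. The order of the steps, the gene annotation release, the handling of reads that match several places and whether strand was used in counting are not given in the sources used here. Genes that overlap another gene, that have an antisense partner or that have near-identical copies are therefore uncertain. The authors deposited 2 tables, 1 per tissue, each holding raw read counts per gene for 12 libraries and FPKM values beside them. The deposited FPKM values were checked against the counts: 0 values differed from the count divided by gene length and library total by more than a small relative tolerance (0.001 of the value), so the FPKM values added nothing to the counts and were not tested. Each table listed 55421 genes, of which 55154 identifiers were found in the GENCODE M21 annotation of mm10, used for positions and gene classes. In each table, 27 symbols that read as dates were renamed from their identifiers.

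All tests started from the deposited counts. Total counts were 23414255 to 27674831 per embryo library and 16400137 to 22113787 per yolk sac library. The tissues were fitted separately, each with all 12 libraries and 1 coefficient per group in edgeR 4.0.16 (R 4.3.3), with TMM scaling, the quasi-likelihood F-test and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. The filterByExpr filter with its defaults (minimum count 10, minimum total count 15) left 19215 genes in embryos and 17755 in yolk sacs, of which 16456 were tested in both. The groups shared 1 estimate of the spread with 6 residual degrees of freedom. The common biological coefficient of variation was 0.087 in embryos and 0.165 in yolk sacs, so that a change of a given size was called less often in yolk sacs. Levels are CPM, counts scaled by the TMM-adjusted library total. Standard errors were taken from the fitted change and its F statistic.

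For each tissue, homozygotes and heterozygotes were compared with WT within each line, the homozygous effect of the CD line was tested against that of the null line as a difference of differences, and the WT groups of the lines were compared. The lines shared no control libraries, so the overlap of their calls was set beside the product of the list sizes over the genes tested. Replicates of each group were compared by a chi-square test of their counts. Per degree of freedom it was 2.95 to 32.3, above sampling noise in every group, so none counted as 1 library deposited again.

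The 24 gene lists covered H3K36 methylation factors, primitive erythroid, endothelial, visceral endoderm, extraembryonic mesoderm, cardiac, neural, neural crest, somite and Hox genes, hypoxia and glycolysis, p53 targets, the integrated stress response, interferon response, germline genes, imprinted genes, trophoblast and decidua, parietal endoderm, leukocytes, proliferation, immediate early genes, cholesterol synthesis, mitochondrially encoded transcripts and sex-linked genes. They were written by hand from general knowledge. Lists were tested against all other genes with camera in limma 3.58.1 at its preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of called members are given over all genes tested and adjusted over the list alone.

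Genes are named by a rule: Setd2; up to 8 higher and 8 lower genes of smallest p per homozygous comparison, at 1 log2 unit or more and 1 CPM or more, with both homozygous libraries on the same side of both WT libraries; up to 4 called members of smallest p per list; up to 4 genes each way for the smaller comparisons; and up to 8 genes called in both lines or both tissues. Where nothing passed, the 3 genes of smallest p are given as values, and sex-linked genes in part for every library. Predicted genes and pseudogenes were passed over unless a count of 5 or fewer consisted of them. Any gene outside the rule is said to be chosen after its values were seen.

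The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were the DESeq2 1.42.0 Wald test, RLE size factors, library totals alone, no filter on low counts, globin and mitochondrial genes removed, only the compared groups in the fit, heterozygotes as or within the reference, the replicate number as a block and each library left out in turn. A sex term (summed CPM of Y-linked genes), list tests with each library left out, and 1 yolk sac fit without CD HE replicate 2 were added after seeing the data. With 1 coefficient per group, the sex term was estimated mainly from the groups named above whose replicates differed in sex transcripts. Any other difference between those replicates also entered the term.

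The procedure was tested on simulated data, drawn from the means and library sizes of the real samples. In embryos (null HO against WT, 18776 genes) edgeR recovered 52.9% of genes changed 1.5-fold, 88.5% at 2-fold and 97.1% at 4-fold, with 8 false calls among 166. In yolk sacs (null HO against WT, 17176 genes) the shares were 11.4%, 49.2% and 84.5%, with 4 false calls among 101. DESeq2 made 15 false calls among 177 in the simulated embryos and 28 among 157 in the simulated yolk sacs. With nothing changed (CD HO against WT), edgeR made 1 call in each tissue. Camera with the estimated correlation found a jointly moved list in simulated embryos (adjusted p = 5.1e-05) but not yolk sacs (adjusted p = 0.139). Lists of co-varying genes were not tested.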

Results

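Transcripts were counted in whole embryos and in yolk sacs of mice carrying either of 2 mutant alleles of Setd2, the gene for a histone methyltransferase that places trimethylation on lysine 36 of histone H3. By their names, the null allele is meant to remove the protein and the catalytic dead (CD) allele to leave a protein without methyltransferase activity. Neither protein nor activity was measured here. Each tissue gave 12 libraries, 2 for each genotype (WT, HE, HO) of each line. Embryo libraries held 23414255 to 27674831 counts and yolk sac libraries 16400137 to 22113787. Levels are given as CPM, mean ± SD over 2 libraries unless said otherwise, and changes as log2 fold changes with their standard error (SE). Adjusted p-values of genes are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR adjusted p), and those of gene lists from camera (camera adjusted p).

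Setd2 (ENSMUSG00000044791, mm10 chromosome 9, 110532597 to 110618633) followed the labels in null embryos. It stood at 231 ± 2.12 CPM in WT, 163 ± 8.27 in HE and 98.7 ± 7.63 in HO. The homozygous fall was -1.23 (SE 0.07, edgeR adjusted p = 4.67e-07), while the heterozygous change of -0.50 (SE 0.07) did not pass (edgeR adjusted p = 0.057; 0.0251 with library totals alone). In CD embryos Setd2 was 239 ± 21.7 CPM in WT, 227 ± 6.37 in HE and 215 ± 3.86 in HO, a homozygous change of -0.15 (SE 0.07, edgeR adjusted p = 0.161). Without CD WT replicate 1 the change was -0.24 and passed. In the CD yolk sacs it was 184 ± 8.59, 180 ± 13.3 and 193 ± 1.44 CPM (homozygous change 0.07, SE 0.09, edgeR adjusted p = 0.728). In the null yolk sacs the level went against the labels. The libraries labelled WT held 108 ± 8.12 CPM and the heterozygotes 117 ± 3.99 (change 0.11, SE 0.09, edgeR adjusted p = 1), against 77.3 ± 2.38 in HO. The fall from the libraries labelled WT to HO was -0.49 (SE 0.09, edgeR adjusted p = 0.0113), and it did not pass without the null library labelled WT replicate 2 (-0.42) or without null HO replicate 1 (-0.47). The part of Setd2 that the null allele lacks is not given in the sources used here, so reads from outside that part could still be counted.

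**Figure D1:**
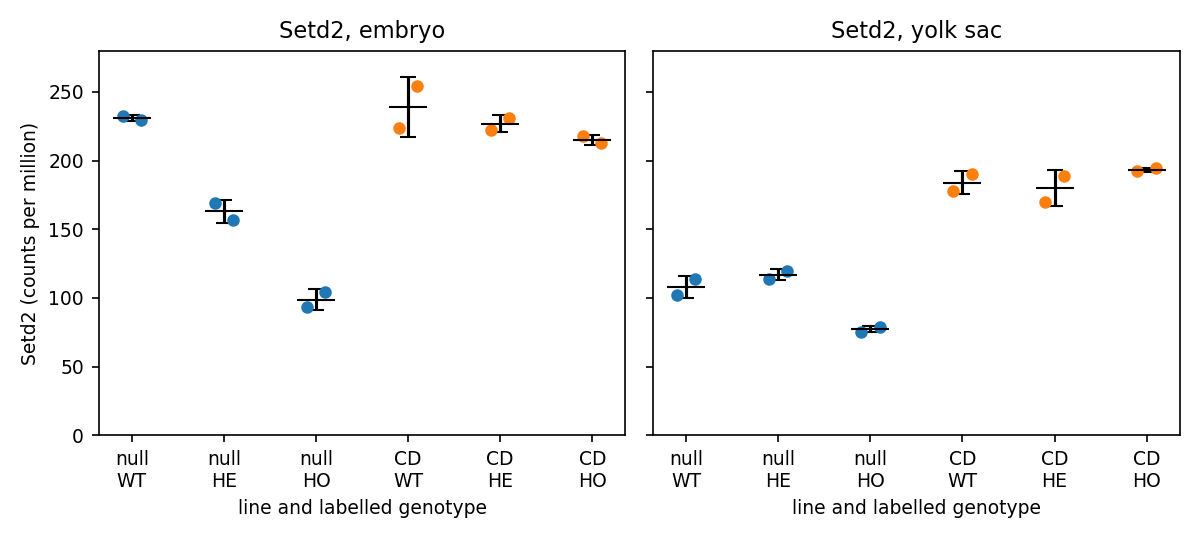
Setd2 level in CPM (vertical axis) for each library, by line and labelled genotype, in embryos (left) and yolk sacs (right); points are libraries, horizontal marks the mean of 2 and bars the SD. Null embryos step down from 231 to 163 to 98.7 CPM, while the null yolk sac libraries labelled WT (108) lie at the level of the heterozygotes (117).

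Transcripts that tell sex differed between groups. In embryos, Xist lay between 1266 and 2148 CPM with Ddx3y, Eif2s3y, Kdm5d and Uty at 0.239 CPM or less in both null WT, null HO replicate 2, CD HE replicate 1 and both CD HO libraries. The other embryo libraries (both null HE, null HO replicate 1, both CD WT and CD HE replicate 2) held Ddx3y at 53.7 to 76.9 CPM and Xist at 0.963 to 3.2. In yolk sacs, null HE replicate 1, null HO replicate 1 and both CD HO libraries held Ddx3y at 105.8 to 122.3 CPM and Xist at 2.85 to 18.1. CD HE replicate 2 held both, Xist at 896.6 CPM and Ddx3y at 88.3, and the other yolk sac libraries held Xist at 1351 to 1576 CPM. WT and HO therefore differed in sex in the CD line in both tissues, and null WT from null HE and CD WT in embryos. The antisense gene Tsix lay at 0.108 to 0.858 CPM in embryos and 1.08 to 3.47 CPM in yolk sacs.

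Homozygous null embryos were first compared with their WT to ask what the null allele does to the embryo. Targets of the tumour suppressor p53 were among the genes of smallest p that rose. For the genes named from each homozygous comparison by p, both HO libraries lay on the same side of both WT libraries. Trp53inp1, a stress protein that acts with p53, rose from 25 ± 1.2 to 114 ± 2.37 CPM (2.19, SE 0.082, edgeR adjusted p = 3.33e-08), and Ccng1, the cyclin G1 gene, from 61.9 ± 2.98 to 310 ± 56.7 CPM (2.32, SE 0.12, edgeR adjusted p = 1.98e-07). The death receptor genes Eda2r (2.90) and Tnfrsf10b (2.11) and the stress sensor Sesn2 (2.48) rose with them, as did Foxo3 (1.28), a transcription factor of stress and survival. Among the genes that fell were several zinc finger genes, among them Zfp850, from 39.2 ± 0.664 to 2.13 ± 0.64 CPM (-4.19, SE 0.14, edgeR adjusted p = 2.02e-08), with Zfp873 (-4.22), Zik1 (-2.42) and Zfp26 (-1.60). Pole, the catalytic subunit of the leading-strand DNA polymerase, fell from 200 ± 5.91 to 59.5 ± 6.69 CPM (-1.75, SE 0.069, edgeR adjusted p = 3.42e-08), and Hjurp, the chaperone of the centromeric histone, fell by 1.16.

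By lists, 23 of 34 tested p53 targets rose and 1 fell (25 adjusted over the list alone; camera adjusted p = 5.34e-26, and adjusted p = 0.133 with an estimated correlation). Of 39 genes of hypoxia and glycolysis, 26 rose and 0 fell (32 adjusted over the list alone; camera adjusted p = 1.54e-09, adjusted p = 0.4 with an estimated correlation). Members included the angiogenic factor Vegfa (0.70), the phosphofructokinase gene Pfkp (1.69) and the collagen hydroxylase gene P4ha2 (1.06). The integrated stress response rose in 24 of 37 members and fell in 1 (28 adjusted over the list alone; camera adjusted p = 1.65e-11, adjusted p = 0.4 with an estimated correlation). Members included Chac1, a glutathione-degrading enzyme (4.39), and the amino acid transporter gene Slc7a3 (2.57). Visceral endoderm genes rose in 16 of 43 and fell in 3 (20 adjusted over the list alone; camera adjusted p = 0.00452, adjusted p = 0.551 with an estimated correlation). The endocytic receptor gene Lrp2 was at 1.34, Npnt at 0.81 and Vtn, which fell, at -1.52. Imprinted genes rose in 14 of 39 and fell in 4 (19 adjusted over the list alone; camera adjusted p = 0.0383, adjusted p = 0.551 with an estimated correlation). Igf2r was at 0.91 and Nnat at -1.43. This list did not pass without null WT replicate 1 (0.0675) or null HO replicate 2 (0.252).

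In null embryos, of 50 genes of the neural tube and neurons, 27 fell and 9 rose (39 adjusted over the list alone; camera adjusted p = 4.22e-07, adjusted p = 0.18 with an estimated correlation). The neuronal tubulin gene Tubb3 fell from 28.2 ± 1.76 to 4.83 ± 0.253 CPM (-2.54), and Pax6 (-1.11), a regulator of eye and forebrain, and the Notch ligand gene Dll1 (-0.98) fell too. Somite genes fell in 14 of 28 and rose in 6 (22 adjusted over the list alone; camera adjusted p = 0.00183, adjusted p = 0.4 with an estimated correlation). Foxc1 was at -1.05 and Meox1 at -2.68 (-3.43 without null HO replicate 1). Of 36 primitive erythroid genes, 21 fell and 1 rose (26 adjusted over the list alone; camera adjusted p = 8.59e-06, adjusted p = 0.551 with an estimated correlation). The transferrin receptor gene Tfrc was at -0.48 and the haem enzyme gene Urod at -0.57. The homozygous replicates stood apart here: globin transcripts took 0.128% of counts in replicate 1 and 0.00938% in replicate 2, against 0.204% and 0.304% in WT. Proliferation genes fell in 16 of 36 and rose in 4 (23 adjusted over the list alone; camera adjusted p = 0.0305, adjusted p = 0.4 with an estimated correlation, 0.0627 without null WT replicate 2). Mcm7 was at -0.62 and Pcna at -0.33. Of 15 mitochondrially encoded transcripts, listed beforehand as a sign of RNA quality, 11 fell and 0 rose (12 adjusted over the list alone, camera adjusted p = 0.00238, adjusted p = 0.133 with an estimated correlation). mt-Co1 was at -0.34, and their share of counts was 1.56% and 1.62% in HO against 1.96% and 1.98% in WT. Whether RNA quality lay behind this fall was not tested.

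The remaining lists did not pass in null embryos. Rises and falls were 9 and 5 of 32 for H3K36 methylation factors, where the DNA methyltransferase gene Dnmt3b rose (1.02), 10 and 9 of 52 for endothelial genes, 8 and 9 of 30 for extraembryonic mesoderm, 6 and 3 of 34 for cardiac muscle, 6 and 7 of 20 for neural crest, 3 and 9 of 35 for Hox genes, and 12 and 2 of 31 for the interferon response. They were 7 and 3 of 24 for germline genes, with Ddx4 at 1.55, 7 and 1 of 13 for trophoblast and decidua, 6 and 1 of 15 for parietal endoderm, with the laminin gene Lamb1 at 0.93, 1 and 4 of 15 for leukocytes, 7 and 2 of 28 for immediate early genes, 3 and 4 of 29 for cholesterol synthesis and 0 and 0 of 6 for sex-linked genes. Adjusted over the list alone the counts were 14, 22, 18, 8, 13, 12, 15, 11, 10, 8, 5, 9, 7 and 0 in the same order. Median, mean and test differed in sign for extraembryonic mesoderm (median 0.0942, test down), cardiac muscle (mean -0.0406, test up), germline genes (median -0.0887, test up) and parietal endoderm (mean -0.0181, test up). The trophoblast list (camera adjusted p = 0.0537) passed without any 1 of null WT replicate 1 (0.0494), null WT replicate 2 (0.0332) or null HO replicate 1 (5.33e-08). Its member Prl3d1, a trophoblast hormone gene (7.10), lay at 5.95 ± 8.36 CPM in HO and changed by -0.01 without null HO replicate 2 and 8.10 without null HO replicate 1. It did not pass without null WT replicate 1 (6.19) or null WT replicate 2 (10.22). Without null HO replicate 2 the endothelial (0.043), parietal endoderm (0.0163), immediate early (0.0361), sex-linked (0.043), cholesterol (6.99e-06) and cardiac (0.0487, down) lists passed, and without null HO replicate 1 the extraembryonic mesoderm (0.0305, up), cholesterol (0.0133, up) and cardiac (2.09e-05) lists did.

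Over all genes, 6288 of 19215 tested genes changed in homozygous null embryos, 3120 higher and 3168 lower (32.7% of those tested), of which 889 and 832 changed 2-fold or more. The count fell to 3780 without null WT replicate 1 and to 3655 without null WT replicate 2. On the first principal component, which held 46.9% of the variance in embryos, HO libraries of both lines lay between 45.8 and 65.3 and the other libraries at -0.00687 or below.

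**Figure D2:**
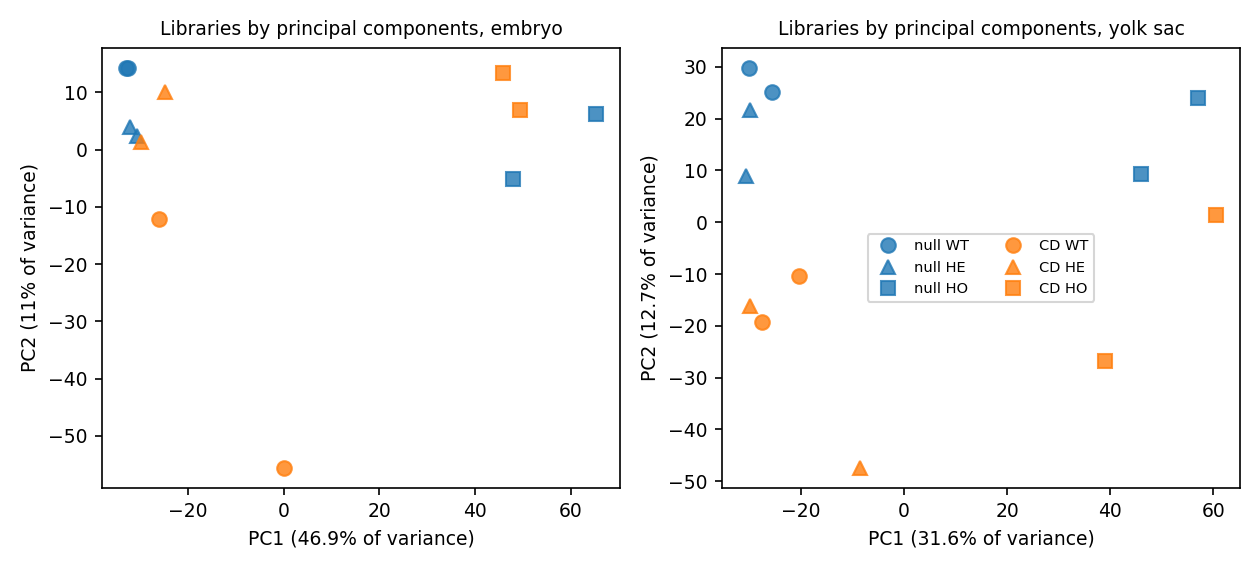
Libraries on the first (horizontal) and second (vertical) principal component of log2 CPM, in embryos (left; 46.9% and 11% of variance) and yolk sacs (right; 31.6% and 12.7%); each point is a library, colour gives the line and shape the labelled genotype. Homozygotes lie to the right in both tissues, and embryo CD WT replicate 2 stands apart from its group at -55.6 on the second component.

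Homozygous CD embryos were compared with their WT to ask what the CD allele does, and p53 targets rose here too. Trp53inp1 went from 21.5 ± 2.65 to 69 ± 0.813 CPM (1.68, SE 0.083, edgeR adjusted p = 1.59e-07), Ccng1 from 53.4 ± 9.47 to 223 ± 1.11 (2.06, SE 0.12, edgeR adjusted p = 8.19e-07), and Eda2r rose by 2.22 and Sesn2 by 1.95. The strongest fall by p was that of Rpl29, a ribosomal protein gene (mm10 chromosome 9, 106429454 to 106431568), from 305 ± 5.73 to 28 ± 2.79 CPM (-3.44, SE 0.09, edgeR adjusted p = 8.36e-10). Rpl29 has many near-identical copies in the genome, so its level is uncertain. Zfp850 fell from 39.3 ± 0.504 to 1.55 ± 0.238 CPM (-4.67, SE 0.15, edgeR adjusted p = 5.21e-09), and Pole (-1.58), Zik1 (-2.24), Zfp26 (-1.53), Zfp948 (-2.69) and the chloride channel gene Clcn4 (-3.26) fell as well.

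Of 34 p53 targets, 24 rose and 0 fell (27 adjusted over the list alone; camera adjusted p = 7.93e-30, and adjusted p = 0.0473 with an estimated correlation). Hypoxia and glycolysis genes rose in 20 of 39 and fell in 0 (31 adjusted over the list alone; camera adjusted p = 1.75e-12, adjusted p = 0.466 with an estimated correlation). Pfkp was at 1.29 and P4ha2 at 0.76, although neither gene passed with a sex term (1.05 and 0.62). The integrated stress response rose in 20 of 37 and fell in 0 (24 adjusted over the list alone; camera adjusted p = 3.33e-14, adjusted p = 0.426 with an estimated correlation). Chac1 was at 4.16 and the translation inhibitor gene Eif4ebp1 at 0.81. Somite genes fell in 9 of 28 (9 adjusted over the list alone; camera adjusted p = 5.2e-05, adjusted p = 0.426 with an estimated correlation). Meox1 was at -1.66, which did not pass with a sex term (-1.26). Cholesterol synthesis fell in 8 of 29 and rose in 0 (11 adjusted over the list alone; camera adjusted p = 4.1e-06, adjusted p = 0.583 with an estimated correlation). Members included the sterol reductase gene Tm7sf2 (-1.57). Mitochondrially encoded transcripts fell in 10 of 15 (11 adjusted over the list alone; camera adjusted p = 4.1e-06, and adjusted p = 0.0458 with an estimated correlation). mt-Cytb was at -0.60, and their share was 1.46% and 1.52% in HO against 1.98% and 1.91% in WT. Primitive erythroid genes fell in 2 of 36 and rose in 1 (0 adjusted over the list alone; camera adjusted p = 0.027, adjusted p = 0.831 with an estimated correlation). This list did not pass without CD WT replicate 1 (0.282) or CD HO replicate 1 (0.881), and turned to a rise with a sex term. The sex term rested mainly on null HO and CD HE. The erythroid list median was -0.326 in null HO replicate 1 (male) and -2.69 in replicate 2 (female). That difference entered the sex term, so the turn cannot be read as an effect of sex. The globin share was 0.06% and 0.157% in CD HO and 0.225% and 0.111% in CD WT.

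Visceral endoderm genes fell in 17 of 43 and rose in 2 (26 adjusted over the list alone; camera adjusted p = 0.000216, adjusted p = 0.583 with an estimated correlation). This fall followed a single library: CD WT replicate 2 stood at a list median of 1.23 above the tissue mean on the log2 scale, against 0.107 in CD WT replicate 1, and the list did not pass without replicate 2 (0.236). Trf, the transferrin gene, was at 12.7 ± 6.81 CPM in WT and 0.63 ± 0.0792 in HO (-4.33, and -3.66 without CD WT replicate 2), while Npnt rose by 0.57. Neural genes fell in 10 of 50 and rose in 4 (17 adjusted over the list alone; camera adjusted p = 0.0502). Tubb3 was at -1.42 and Dll1 at -0.80. The list passed without CD WT replicate 2 (0.000774) or CD HO replicate 1 (0.0156). Without CD WT replicate 2 the Hox (0.00339), endothelial (0.038) and extraembryonic mesoderm (0.0301) lists passed too, and Hox genes also without CD HO replicate 2 (0.011). For H3K36 methylation factors (median 0.0175, test down) and trophoblast genes (mean -0.0749, test up), which did not pass, the signs differed. Among lists that did not pass, the imprinted gene Nnat fell by 0.80 and the histocompatibility gene H2-K1 by 1.49.

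In all, 3087 of 19215 genes changed in homozygous CD embryos, 1330 higher and 1757 lower (16.1% of those tested). The count was 1914 without CD WT replicate 1, 1355 without CD HO replicate 1 and 1272 without CD HO replicate 2. It was 300 with the sex term. Both WT libraries of this line were male and both HO libraries female.

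The homozygous effects of the lines were compared to ask whether the 2 alleles act on the same transcripts. Of the called genes, 2300 were shared with the same direction in embryos, 951 higher and 1349 lower, against 216 and 290 for independent lists, and 3 were called in opposite directions. Zfp850, Pole, Zik1, Zfp26, Zfp873, Clcn4 and Hjurp were among the shared falls and Trp53inp1 among the shared rises. Of the null calls 92.9% had the same sign in CD embryos, and of the CD calls 96.2% had the same sign in null embryos. Across genes, which are not independent replicates, the effects correlated at r = 0.528. The median size of the shared changes was 0.622 on the log2 scale in null embryos and 0.489 in CD embryos. The shared count was 1303 without CD WT replicate 1, 1159 without CD HO replicate 1, 1076 without CD HO replicate 2, 1135 with only the groups compared in the fit and 276 with the sex term.

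Only 4 genes passed the test of the difference between the homozygous effects (edgeR; 2580 at an unadjusted p under 0.05; 197 by DESeq2). Rpl29 fell in CD alone (difference -3.55, SE 0.12, edgeR adjusted p = 1.55e-08). Setd2 fell in null embryos and not in CD embryos (difference 1.08, SE 0.10, edgeR adjusted p = 0.000721; 1.05 with the sex term, where it did not pass at adjusted p = 0.14). The predicted genes Gm10709 and Gm8210 were the others and were named after their values were seen. Gm10709 lay at 0.153 and 0.0429 CPM in CD HO and 11.4 and 11.2 in CD WT. Gm8210 lay at 24.5 and 25 CPM in CD HO and 0.12 and 0.0833 in CD WT. The count was 1003 without null HO replicate 1, 1048 without CD WT replicate 1, 15 without null HO replicate 2 and 7 without CD HO replicate 2.

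**Figure D3:**
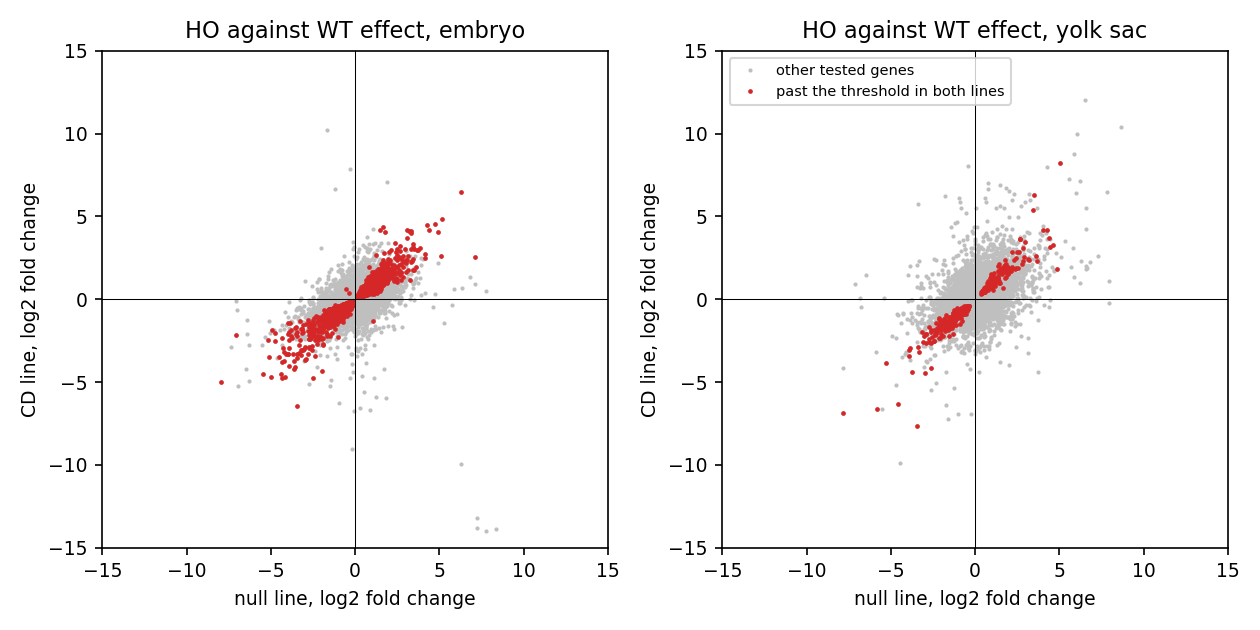
Homozygous against WT log2 fold change in the null line (horizontal) and the CD line (vertical) for each tested gene, in embryos (left) and yolk sacs (right); red points are genes past the threshold in both lines. Red points lie almost wholly in the quadrants of shared direction, with 3 of opposite direction in embryos and 0 in yolk sacs.

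Few genes passed in heterozygous embryos. In the null line both WT libraries were female and both HE libraries male, so genotype and sex cannot be parted there. In that line 2 genes passed in edgeR (464 at an unadjusted p under 0.05; 8 by DESeq2), the pseudogene Tma7-ps, higher, and the unplaced entry AC149090.1, lower, named after their values were seen. Tma7-ps lay at 21.4 and 20.7 CPM in null HE and 11.7 and 11.6 in null WT, and AC149090.1 at 4.33 and 3.74 against 15.6 and 14.8. In the CD line 3 genes passed (1693 at an unadjusted p under 0.05; 53 by DESeq2). Rpl29 fell to 161 ± 6.7 CPM from 305 ± 5.73 (-0.92, SE 0.08, edgeR adjusted p = 0.000581). Gm8210, at 11.5 and 12.4 CPM, and Tma7-ps, at 20.1 and 20.7 CPM, rose, both named after their values were seen and both sharing sequence with other genes. The null count was 0 with the sex term and 1 or 0 without any 1 library of the groups compared, and the CD count was 849 without CD WT replicate 1.

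By lists, 5 passed in null HE embryos with 0 called members. Mitochondrially encoded transcripts rose (camera adjusted p = 4.68e-05, adjusted p = 0.0386 with an estimated correlation), against a fall in null HO, and did not pass with the sex term (0.0681). Sex-linked genes passed with the same values and turned direction with the sex term (0.844). Cholesterol synthesis rose (0.000265), primitive erythroid genes rose (0.00364) and extraembryonic mesoderm fell (0.0288), none of them with an estimated correlation (0.974). The erythroid list did not pass without null WT replicate 1 (0.843) or null HE replicate 2 (0.215) and turned to a fall with the sex term (3.3e-09). The mesoderm list did not pass without null WT replicate 1 (0.0644), null WT replicate 2 (0.198) or null HE replicate 2 (0.871), and turned direction with the sex term (0.323).

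In CD HE embryos 10 lists passed with 0 called members, and 0 with an estimated correlation (adjusted p = 0.372 to 0.751). Visceral endoderm fell (camera adjusted p = 7.2e-23) from a WT group whose replicate 2 was high in these genes, and neural genes rose (1.31e-05); both passed with each library left out. Hypoxia and glycolysis (7.44e-08), cholesterol synthesis (0.0075), interferon (0.00828), Hox (0.0253), somite (0.0266) and H3K36 methylation (0.0462) lists fell, and erythroid genes (9.72e-06) and p53 targets (0.0413) rose. Without CD WT replicate 2 the hypoxia (0.734), somite (0.108), H3K36 (0.902) and p53 (0.993) lists did not pass, and without CD WT replicate 1 the cholesterol (0.0517) and Hox (0.766) lists did not. Without CD HE replicate 1 the cholesterol (0.15), Hox (0.0669), somite (0.0669), H3K36 (0.231) and p53 (0.128) lists did not pass. Without CD HE replicate 2 the interferon (0.0913), Hox (0.0684), somite (0.0829), erythroid (0.0684) and p53 (0.0665) lists did not. The Hox (0.153), somite (0.306) and H3K36 (0.126) calls ended with the sex term, and the last also with library totals alone (0.119).

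The WT embryos of the lines were compared too. Both null WT libraries were female and both CD WT libraries male, so line and sex cannot be parted in this comparison. The test passed 6 genes in edgeR (2835 at an unadjusted p under 0.05; 385 by DESeq2). Greb1, an oestrogen-regulated gene, was 200 ± 26 CPM in CD WT and 129 ± 5.24 in null WT (0.63, SE 0.079, edgeR adjusted p = 0.0151). The imprinted growth factor gene Igf2 was 163 ± 7.5 and 119 ± 1.52 CPM (0.46, SE 0.059, edgeR adjusted p = 0.0151). Amd2, a near copy of a polyamine synthesis gene and so uncertain, was 1.75 ± 0.301 and 12.4 ± 0.346 CPM (-2.82). The predicted genes Gm11868, Gm13456 and Gm11942 were higher in CD WT and were named after their values were seen. Greb1 and Igf2 did not pass without null WT replicate 1 (0.67 and 0.47) or null WT replicate 2 (0.59 and 0.45), nor Igf2 without CD WT replicate 2 (0.41), and the count was 1623 without CD WT replicate 1, 2 without null WT replicate 1 and 0 with the sex term. By lists, visceral endoderm (camera adjusted p = 4.25e-22) and hypoxia and glycolysis (1.32e-09) were higher in CD WT and neural genes lower (0.00116), each with every library left out in turn. Trophoblast (0.0103), cholesterol (0.0249), somite (0.0432) and sex-linked (0.0432) lists were also higher, and p53 (0.0315) and erythroid (0.0432) lists lower. None of the 9 passed with an estimated correlation (adjusted p = 0.381 to 0.873). Without null WT replicate 1 the trophoblast (0.0503), cholesterol (0.0896), somite (0.106), sex-linked (0.0896) and p53 (0.0561) lists did not pass. Without null WT replicate 2 the somite (0.069), sex-linked (0.115) and erythroid (0.76) lists did not, without CD WT replicate 1 the trophoblast (0.215), cholesterol (0.0942) and sex-linked (0.145) lists, and without CD WT replicate 2 the somite (0.0723), p53 (0.555) and erythroid (0.555) lists. With the sex term the somite call ended (0.591) and the sex-linked list turned direction (0.592). The erythroid call ended with RLE size factors (0.0511) or library totals alone (0.0715).

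In yolk sacs of the null line, homozygotes were compared with the libraries labelled WT, whose Setd2 level went against that label. Gja5, the gap junction gene of arterial endothelium, fell from 47.2 ± 6.98 to 0.82 ± 0.625 CPM (-5.80, SE 0.47, edgeR adjusted p = 9.75e-05; -6.95 without null HO replicate 1). The protocadherin gene Pcdh17 fell from 25.9 ± 2.19 to 2.55 ± 0.826 CPM (-3.35, SE 0.25, edgeR adjusted p = 9.75e-05), and Col14a1 (-2.01), the lysosomal reductase gene Ifi30 (-1.36) and Clcn4 (-1.90) fell too. Among the rises, Nrip3 went from 2.94 ± 0.556 to 26.9 ± 1.54 CPM (3.19, SE 0.26, edgeR adjusted p = 9.75e-05), and the basement membrane gene Lama1 (1.67), Tspoap1 (3.13), the lipid transporter gene Abca2 (2.17) and Dkc1, the dyskerin gene (1.07), rose.

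Endothelial genes fell in 12 of 51 and rose in 0 (23 adjusted over the list alone; camera adjusted p = 1.31e-10, adjusted p = 0.379 with an estimated correlation). The adrenomedullin receptor gene Calcrl was at -2.14. Extraembryonic mesoderm fell in 9 of 30 and rose in 2 (13 adjusted over the list alone; camera adjusted p = 2.97e-06, adjusted p = 0.379 with an estimated correlation), with the collagen genes Col1a1 (-2.01), Col3a1 (-2.30) and Col1a2 (-1.74). Visceral endoderm fell in 9 of 47 and rose in 0 (10 adjusted over the list alone; camera adjusted p = 0.00012, adjusted p = 0.379 with an estimated correlation). Its member Cubn, an endocytic receptor gene, was 5920 ± 388 CPM in HO and 9260 ± 557 in the libraries labelled WT (-0.65), and did not pass without null WT replicate 1 (-0.59), null WT replicate 2 (-0.71) or null HO replicate 1 (-0.59). Leukocyte markers fell in 4 of 24 (11 adjusted over the list alone; camera adjusted p = 0.002, adjusted p = 0.379 with an estimated correlation). The Fc receptor gene Fcgr3 was at -2.16. Parietal endoderm, a neighbouring tissue, rose in 7 of 15 and fell in 0 (11 adjusted over the list alone; camera adjusted p = 3.97e-10, adjusted p = 0.225 with an estimated correlation), with Lama1 from 159 ± 7.89 to 503 ± 129 CPM. Of p53 targets 6 of 35 rose and 1 fell (16 adjusted over the list alone; camera adjusted p = 1.25e-05, adjusted p = 0.379 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a was at 1.31 and did not pass without null WT replicate 1 (edgeR adjusted p = 0.0561), null WT replicate 2 (0.0746) or null HO replicate 1 (0.067). Proliferation genes rose in 4 of 36 and fell in 0 (10 adjusted over the list alone; camera adjusted p = 1.56e-06, adjusted p = 0.379 with an estimated correlation). The replication licensing gene Cdc6 was at 0.99.

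Neural genes rose in 2 of 25 and fell in 1 in null yolk sacs (3 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.225 with an estimated correlation). Erythroid genes rose in 2 of 36 and fell in 1 (3 adjusted over the list alone; camera adjusted p = 0.00849, adjusted p = 0.824 with an estimated correlation). This list did not pass without null HO replicate 1 (0.191) or with a sex term, and globin took 1.93% and 1.28% of counts in HO and 1.21% and 1.36% in the libraries labelled WT. Immediate early genes rose in 4 of 28 and fell in 1 (7 adjusted over the list alone; camera adjusted p = 0.0387, adjusted p = 0.404 with an estimated correlation). Ccn1 was at 1.40 and Ccn2 at 1.48. This list did not pass without null WT replicate 2 (0.115) or null HO replicate 1 (0.0767), or with a sex term. Of 15 mitochondrially encoded transcripts, 0 passed. In all, 1113 of 17755 genes changed, 408 higher and 705 lower. The count was 290 without null WT replicate 1, 165 without null WT replicate 2, 169 without null HO replicate 1, 602 without null HO replicate 2 and 682 with the sex term. The integrated stress response (0.0277 without null WT replicate 2), interferon (0.00281 without null HO replicate 1), germline (0.0249 without null HO replicate 2) and trophoblast (0.00159 without null WT replicate 1) lists passed only with a library left out or, for the first pair, also with a sex term. Median, mean and test differed in sign for hypoxia, neural crest, Hox and imprinted genes, none of them past the threshold.

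**Figure D4:**
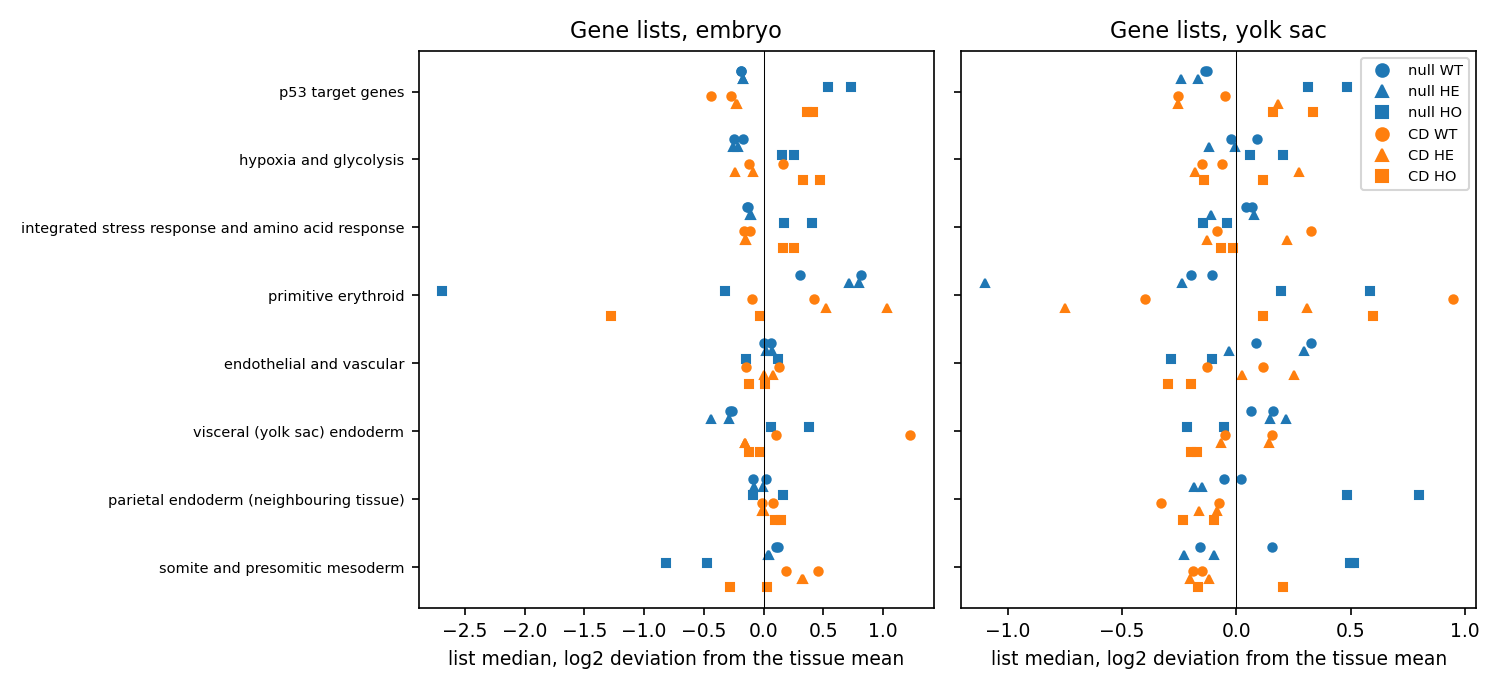
Median over the tested members of 8 gene lists of the log2 deviation of each library from the mean of the 12 libraries of its tissue (horizontal), in embryos (left) and yolk sacs (right); each point is a library, colour gives the line and shape the labelled genotype. Embryo CD WT replicate 2 lies at 1.23 for visceral endoderm, and embryo null HO replicate 2 at -2.69 for primitive erythroid genes.

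Homozygous CD yolk sacs were compared with the libraries labelled WT in their line. The genotype label of CD WT replicate 2 is in doubt, since Rpl29 (148.7 CPM) and Gm8210 (9.49 CPM, named after its values were seen) lay near their CD HE levels there. This holds for each yolk sac comparison with CD WT. Gja5 fell from 31.7 ± 3.16 to 0.306 ± 0.0938 CPM (-6.63, SE 0.54, edgeR adjusted p = 1e-04), Pcdh17 from 23.3 ± 1.85 to 2.54 ± 0.29 (-3.19, SE 0.25, edgeR adjusted p = 9.17e-05) and Ifi30 from 163 ± 7.81 to 49.2 ± 6.86 (-1.73, SE 0.11, edgeR adjusted p = 2.18e-05). The lymphatic growth factor gene Vegfc fell by 2.55 and Clcn4 by 2.24. Nrip3 (2.39), Tspoap1 (2.44), Abca2 (1.95), the calcium channel subunit gene Cacna2d2 (3.10) and the antiviral deaminase gene Apobec3 (1.94) rose. Rpl29 fell from 188 ± 55.4 to 18.6 ± 4.28 CPM (-3.33, SE 0.21, edgeR adjusted p = 2.18e-05), with the caution about its copies given above for embryos. The WT replicates stood apart in this gene, at 227.1 CPM in replicate 1 and 148.7 in replicate 2, the latter within the range of 116 to 154 CPM in CD HE.

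Endothelial genes fell in 6 of 51 and rose in 0 in CD yolk sacs (9 adjusted over the list alone; camera adjusted p = 6.12e-05, adjusted p = 0.748 with an estimated correlation), visceral endoderm in 6 of 47 (13 adjusted over the list alone; camera adjusted p = 0.000658, adjusted p = 0.748 with an estimated correlation), and the endothelial call ended with a sex term. Of 35 p53 targets 1 rose, Ddit4l (15 adjusted over the list alone; camera adjusted p = 0.000658, adjusted p = 0.748 with an estimated correlation). This call too ended with a sex term, and Ddit4l, at 2.64, did not pass without CD WT replicate 1 (2.07), CD WT replicate 2 (3.58), CD HO replicate 1 (2.48) or CD HO replicate 2 (2.75). Neural genes rose in 1 of 25 (2 adjusted over the list alone; camera adjusted p = 0.00252, adjusted p = 0.186 with an estimated correlation). Trophoblast and decidua genes passed as a list with 0 of 16 members called (0 adjusted over the list alone; camera adjusted p = 0.0349, adjusted p = 0.748 with an estimated correlation) and did not pass without CD WT replicate 2 (0.133) or CD HO replicate 1 (0.903), or with library totals alone (0.0597). Proliferation genes rose in 4 of 36 (4 adjusted over the list alone; camera adjusted p = 0.0309, adjusted p = 0.748 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at 0.68. This list did not pass without CD WT replicate 1 (0.334), CD HO replicate 1 (0.111) or CD HO replicate 2 (0.0566). The trophoblast and proliferation calls ended with a sex term as well. Extraembryonic mesoderm fell in 3 of 30 and rose in 2 without passing (camera adjusted p = 0.0521; 0.00376 without CD WT replicate 2, 0.0198 without CD HO replicate 1 and 0.0452 with library totals alone). Col1a1 was at -1.41. Primitive erythroid genes passed as a fall without CD WT replicate 1 (2.73e-07) and as a rise without CD WT replicate 2 (3.7e-08), Hox genes passed without CD WT replicate 1 (0.0403) or CD HO replicate 2 (0.00499), the integrated stress response without CD WT replicate 1 (2.73e-07) or CD HO replicate 1 (0.0481), and cholesterol synthesis without CD WT replicate 2 (0.04) or CD HO replicate 1 (0.0106). With the sex term erythroid (6.51e-08), integrated stress response (0.000271) and mitochondrially encoded (0.0131) lists passed as falls, and Hox (0.0102) and cholesterol (0.0445) lists as rises. The cholesterol list also passed with library totals alone (0.0452). The globin share was 0.828% and 2.56% in WT and 1.15% and 1.62% in HO. For leukocyte markers, which did not pass, the median was 0.024 and the test down.

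In all, 560 of 17755 genes changed in homozygous CD yolk sacs, 225 higher and 335 lower (59.8% lower). With library totals alone 297 were higher and 240 lower (44.7% lower). The count was 140 without CD WT replicate 1, 179 without CD WT replicate 2, 1074 without CD HO replicate 1, 66 without CD HO replicate 2 and 102 with the sex term. Both WT libraries were female and both HO libraries male. The lines shared 378 calls of the same direction in yolk sacs, 133 higher and 245 lower (64.8% lower; 52.1% lower with library totals alone), against 5 and 13 for independent lists, and 0 were called in opposite directions. Of the null calls 97.4% had the same sign in CD yolk sacs and of the CD calls 98.4% had the same sign in null yolk sacs, with r = 0.544 across genes, which are not independent replicates. The drug-metabolising esterase gene Ces2b, at -1.51 in the null and -1.40 in the CD line, was among the shared falls. The null side of these counts rests on the libraries labelled WT, and the CD side on a WT group whose replicate 2 has a doubtful label. The shared count was 121 without null WT replicate 1, 114 without null WT replicate 2, 119 without null HO replicate 1, 235 without null HO replicate 2, 108 without CD WT replicate 1, 137 without CD WT replicate 2 and 59 without CD HO replicate 2. It was 82 with the sex term, 48 with only the groups compared in the fit, 691 by DESeq2 and 980 with no filter.

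The homozygous effects in yolk sacs differed between the lines in 5 genes, all lower in CD (edgeR; 588 at an unadjusted p under 0.05; 13 by DESeq2). They were Rpl29 (-3.33, SE 0.28, edgeR adjusted p = 0.000905), the fatty acid binding protein gene Fabp3 (-3.12, SE 0.42, edgeR adjusted p = 0.0293), and Gm10709, Rpl34-ps1 and Rps27a-ps2, which share sequence with ribosomal protein genes, are uncertain and were named after their values were seen. Fabp3 lay at 25.6 and 14.0 CPM in null HO and 4.80 and 4.28 in the libraries labelled WT, and its difference did not pass without null WT replicate 1 (-3.21), null WT replicate 2 (-3.04), null HO replicate 1 (-2.62), CD WT replicate 1 (-2.87) or CD HO replicate 2 (-3.00). The count was 2 without null WT replicate 1 or 2, 3 without null HO replicate 1, 28 without CD HO replicate 1 and 1 without CD HO replicate 2.

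Heterozygous yolk sacs gave 0 called genes in edgeR in either line, with 360 (null) and 665 (CD) at an unadjusted p under 0.05 and 2 and 7 calls by DESeq2. Ighm, the immunoglobulin heavy chain gene of B cells, was among the genes of smallest p in both lines without passing, at 3.64 ± 1.82 CPM in null HE and 29.7 ± 7.52 in the libraries labelled WT (edgeR adjusted p = 0.225), and at 0.116 ± 0.091 CPM in CD HE and 2.22 ± 0.525 in CD WT (edgeR adjusted p = 0.995). The B cell genes Igkc (11.1 ± 3.72 CPM) and Pax5 (3.17 ± 1.06 CPM) were also at their highest group means of the null line in the libraries labelled WT. The CD count was 7 without CD WT replicate 2 and 1 without CD HE replicate 2, and the null count 1 without null HE replicate 1.

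By lists, 11 passed in null HE yolk sacs against the libraries labelled WT with 0 called members, and 0 with an estimated correlation (adjusted p = 0.471 to 0.83). Mitochondrially encoded transcripts rose (camera adjusted p = 1.39e-07) and immediate early genes fell (0.00305), each with every library left out in turn. Erythroid (4.58e-10), leukocyte (6.37e-05), extraembryonic mesoderm (0.00951), interferon (0.00951), germline (0.0204), endothelial (0.0322) and parietal endoderm (0.0366) lists fell. Cholesterol (0.00951) and visceral endoderm (0.0392, with a mean of -0.0136) lists rose. Without null WT replicate 2 the leukocyte (0.214), interferon (0.214), cholesterol (0.183) and visceral endoderm (0.941) lists did not pass, and the mesoderm (0.809) and endothelial (0.628) lists turned direction. Without null HE replicate 1 the mesoderm (0.0885), parietal (0.237), cholesterol (0.0874) and visceral endoderm (0.86) lists did not pass, and the endothelial list turned direction (0.115). Without null HE replicate 2 the erythroid (0.324), interferon (0.765), germline (0.63) and parietal (0.0579) lists did not pass, nor the germline (0.8) and parietal (0.318) lists without null WT replicate 1. With the sex term the mesoderm (0.529) and visceral endoderm (0.344) calls ended and the endothelial list turned direction (0.157), and the visceral endoderm call ended with library totals alone (0.0584).

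In CD HE yolk sacs 9 lists passed with 0 called members, and 0 with an estimated correlation (adjusted p = 0.24 to 0.713). Erythroid (camera adjusted p = 9.29e-10), proliferation (0.00196) and interferon (0.0109) lists fell, and endothelial (0.000434), imprinted (0.00127), hypoxia (0.00182), sex-linked (0.004), neural (0.00842) and extraembryonic mesoderm (0.0353) lists rose. Each of the 9 lost its call without 1 or more libraries. These were, with CD WT replicate 2 left out, the proliferation (0.616), interferon (0.0977), endothelial (0.645), imprinted (0.0977), neural (0.07) and mesoderm (0.935) lists, and the erythroid list turned direction (0.07). Without CD HE replicate 1 they were the erythroid (0.509), proliferation (0.509), endothelial (0.971), imprinted (0.053), neural (0.0589) and mesoderm (0.682) lists. The interferon (0.0643), hypoxia (0.0643), sex-linked (0.0643) and neural (0.0632) lists did not pass without CD WT replicate 1. Without CD HE replicate 2 the interferon (0.943), sex-linked (0.483) and neural (0.0867) lists did not, and the hypoxia list turned direction (0.483). The hypoxia (0.0561) and sex-linked (0.185) calls ended with the sex term.

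Between the WT yolk sacs, 8 genes passed in edgeR (1175 at an unadjusted p under 0.05; 27 by DESeq2). Setd2 itself was 184 ± 8.59 CPM in CD WT and 108 ± 8.12 in the null libraries labelled WT (0.77, SE 0.093, edgeR adjusted p = 0.00895), whereas the embryo WT groups differed by 0.05. The intestinal guanylate cyclase gene Gucy2c (2.25) and the noncoding Platr15, at 15.2 ± 4.9 and 0.101 ± 0.0711 CPM (7.14), were higher in CD WT and Ighm lower (-3.74). Rpl34-ps1, Gm6166, Rpl3-ps1 and Rpl3-ps2, all higher in CD WT, share sequence with other genes and were named after their values were seen. Setd2 did not pass without null WT replicate 1 (0.69), null WT replicate 2 (0.84) or CD WT replicate 2 (0.72), nor Gucy2c without null WT replicate 1 (2.31) or 2 (2.18), Platr15 without null WT replicate 2 (6.59; 8.05 without null WT replicate 1), or Ighm without any 1 of the 4 libraries (-4.01 to -3.45), and the count was 3 without null WT replicate 1 and 1 without null WT replicate 2. By lists, extraembryonic mesoderm (camera adjusted p = 7.27e-13), endothelial (9.7e-08), leukocyte (1.24e-06), imprinted (0.000134), Hox (0.000162) and interferon (0.000381) genes were lower in CD WT, each with every library left out in turn. Parietal endoderm (0.00223) and hypoxia (0.0187) lists were also lower, and erythroid (5.36e-07) and proliferation (0.000162) lists higher. None of the 10 passed with an estimated correlation (adjusted p = 0.243 to 0.598). Without CD WT replicate 2 the parietal (0.17) and proliferation (0.216) lists did not pass and the erythroid list turned to a fall (0.0293). The hypoxia list did not pass without null WT replicate 2 (0.23) or CD WT replicate 1 (0.192).

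The tissues were set side by side to ask which transcripts responded in both embryo and yolk sac. In the null line 381 of the 16456 genes tested in both tissues were called in the same direction, 167 higher and 214 lower (68 and 111 for independent lists), and 107 in opposite directions, with r = 0.219 across genes. In the CD line 147 were called in the same direction, 56 higher and 91 lower (16 and 31 for independent lists), and 20 in opposite directions, with r = 0.134 across genes. In both lines and both tissues, 32 genes rose and 50 fell. Clcn4 fell by 3.32 and 3.26 in null and CD embryos and by 1.90 and 2.24 in the yolk sacs and Pcdh17 by 2.55, 2.08, 3.35 and 3.19 in the same order. The matrix protein gene Mxra8 fell by 2.44, 2.16, 2.91 and 2.61 (3.21 in the last without CD HO replicate 2). The null yolk sac values are against the libraries labelled WT.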

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

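The 4 tests on Rpl29, the test of the Setd2 level by genotype in the null yolk sacs and the tests of the genotype of embryo CD WT replicate 2 and of its visceral endoderm level against homozygous embryos were chosen only after the result was seen.

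The homozygous effects of the lines differed by a test of the difference itself in 4 embryo genes and 5 yolk sac genes (edgeR, CD effect minus null effect). In embryos the differences were -3.55 for Rpl29, 1.08 for Setd2, -6.67 for Gm10709 and 8.18 for Gm8210. In yolk sacs, where the null effect is against the libraries labelled WT, they were -3.33 for Rpl29, -6.71 for Gm10709, -3.11 for Rpl34-ps1, -3.12 for Fabp3 and -2.78 for Rps27a-ps2. The Gm10709 and Gm8210 values involve groups near 0 counts and depend on the prior count. The pseudogenes were named after their values were seen.

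Rpl29 fell with each CD allele, to 161 CPM in CD HE and 28 in CD HO embryos from 305 in WT. A move of its reads to copies elsewhere was argued against: the summed CPM of Rpl29 and its copies, 61 genes in all, still changed by -1.95 (SE 0.0736) in CD HO embryos, although reads dropped for matching several places were not excluded. A variant linked to Setd2, which lies on the same chromosome, stayed open: 5 of 258 tested genes within 10 Mb of Setd2 differed between the lines at p under 0.001, against 109 of 18955 elsewhere (odds ratio 3.42, two-sided Fisher's exact p = 0.0189). A response that needs loss of both WT copies was argued against: CD HE embryos, which keep 1, changed by -0.92 (SE 0.08), 52.1% of the fall, and null HO embryos by 0.10 (SE 0.08). An earlier criterion, that the HE share of the fall lie in the middle 95% for 335 other genes that fell 2-fold or more, was met. That range, -132% to 98.9% (median 12%), was too wide to part the cases. A response graded by the number of CD alleles was not tested.

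The yolk sac null libraries labelled WT held heterozygote levels of Setd2. Dilution by other cells was argued against, as the visceral endoderm list differed by a median of -0.03 between the WT yolk sacs of the lines while Setd2 differed by 0.77. Whether these libraries are wild type cannot be told. The 29 genes used were picked in null HE embryos (median 0.96, but 0.18 in CD HE), where sex differed from WT. Their median change was 0.06 in HE against these libraries and 0.04 in null HO yolk sacs, so they do not report genotype here. A lower Setd2 level in null yolk sacs whatever the genotype stayed open too. The yolk sac HE change of 0.11 (SE 0.09), by an earlier criterion against it, is the pattern itself. Null HO against CD WT differed by 0.02 (SE 0.12) between tissues, excluding a lower level only if the allele acts alike in both. HO against its own WT (0.74, SE 0.12) uses the doubted libraries, so cannot tell if it does. A biological difference in Setd2 between the yolk sacs of the lines was not tested.

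Visceral endoderm transcripts were high in embryo CD WT replicate 2. Yolk sac tissue in this library is a candidate explanation: of 45 yolk sac genes, 91.1% gave an implied share within 3-fold of the median of 1.7%, with Apob, Cubn, Afp and Apoa1, named after their values were seen, among those visible. A wrong genotype label was argued against, as Rpl29 was 301 CPM in this library and 309 in replicate 1, which is 2.88% of the fall to CD HO. A state shared with homozygous embryos was argued against as the whole source of this level: the highest list median of the 4 homozygous libraries was 0.379 (SD of the 4 medians 0.219), against 1.23 in this library. The planned test of such a state was a correlation across genes, which are not independent replicates, of the difference between the CD WT replicates with the null HO effect. It gave r = 0.344, which met the criterion set beforehand in favour of a shared state, and 0.351 without the yolk sac genes, against -0.0244 to 0.0254 for the replicate differences of the other groups tested. On the first principal component this library lay at -0.00687, between the other WT and HE embryos (-32.9 to -24.7) and the homozygous ones (45.8 to 65.3). A shared state beyond the visceral endoderm genes therefore stayed open.

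Gene lists differed between the lines by camera on the same difference, and none of these held with an estimated correlation. In embryos the CD effect was the lower for visceral endoderm (camera adjusted p = 1.61e-23), cholesterol synthesis (6.76e-06), trophoblast (0.00643), p53 targets (0.00815), imprinted genes (0.00893) and sex-linked genes (0.0126), and the higher for neural (1.17e-07), erythroid (2.5e-05) and proliferation genes (0.0422). The visceral endoderm difference passed with each library left out (1.83e-21 without CD WT replicate 2, whose list median was 1.23 against 0.107 in replicate 1, and 1.49e-53 without replicate 1). Without null HO replicate 2 the erythroid (0.563), imprinted (0.57), trophoblast (0.334), proliferation (0.138) and cholesterol (0.395) differences did not pass, and without CD WT replicate 1 the p53 (0.375), imprinted (0.0703), trophoblast (0.0703) and proliferation (0.151) differences did not. The p53 difference was 0.52 without null HO replicate 1, the erythroid 0.398, imprinted 0.0723 and proliferation 0.171 without CD HO replicate 2, and proliferation 0.139 without null WT replicate 2. The sex-linked difference was 0.0792 and 0.108 without null WT replicate 1 or 2, 0.13 and 0.197 without CD HO replicate 1 or 2, and turned direction without null HO replicate 1 (0.52).

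In yolk sacs the CD effect was the lower for parietal endoderm (camera adjusted p = 1.02e-13), erythroid (0.000364) and proliferation genes (0.0023), and the higher for extraembryonic mesoderm (0.000648), Hox (0.0023), endothelial (0.00519) and leukocyte genes (0.00625). Parietal endoderm passed with each library left out. Without CD HO replicate 1 the erythroid (0.258), proliferation (0.0805), extraembryonic mesoderm (0.256), Hox (0.42), endothelial (0.388) and leukocyte (0.144) differences did not pass. Without CD WT replicate 2 those of proliferation (0.241), extraembryonic mesoderm (0.0806), Hox (0.0571) and endothelial genes (0.493) did not, and the erythroid difference turned direction (0.0571). Without null HO replicate 1 the erythroid (0.13), proliferation (0.0732), extraembryonic mesoderm (0.152) and endothelial (0.193) differences did not pass, and without null WT replicate 2 the extraembryonic mesoderm (0.179), endothelial (0.373) and leukocyte (0.229) differences did not. The leukocyte difference was 0.206 without null HO replicate 2 and 0.16 without CD WT replicate 1.

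Some genes were called in opposite directions in embryo and yolk sac, and these differences between tissues were not tested. In the null line the embryo and yolk sac changes were 0.38 and -0.65 for Efnb2, 1.69 and -0.42 for Pfkp, 0.54 and -1.46 for Hsd11b2, -0.47 and 1.22 for Pth1r, 1.34 and -1.06 for Dusp5, and 1.05 and -0.61 for Cdh1. They were -0.97 and 2.89 for Crabp1, 0.89 and -0.80 for Bst2, 0.65 and -1.58 for Ifitm3, 0.50 and -0.67 for Slc38a4 and -0.23 and 0.61 for Rrm2, all in yolk sacs against the libraries labelled WT. In the CD line they were -1.79 and 0.94 for Dio3 and 0.72 and -1 for Dusp5. Most of these yolk sac calls ended when a library was left out. In the null line Dusp5 (-1.13, -1, -0.95 and -1.21), Crabp1 (3.2, 2.63, 2.36 and 3.24), Bst2 (-0.8, -0.82, -0.8 and -0.84) and Ifitm3 (-1.85, -1.27, -1.86 and -1.38) did not pass without null WT replicate 1, null WT replicate 2, null HO replicate 1 or null HO replicate 2, in that order. Pfkp did not pass without the first 3 of these (-0.42, -0.43 and -0.3), and Cdh1 without null WT replicate 1 (-0.52). Pth1r (1.08 and 0.88), Slc38a4 (-0.55 and -0.55) and Rrm2 (0.57 and 0.52) did not pass without null WT replicate 2 or null HO replicate 1. In the CD line Dusp5 did not pass in yolk sacs without CD WT replicate 1 (-1.13), CD WT replicate 2 (-0.87) or CD HO replicate 2 (-0.78). In embryos Dio3 (-1.61) and Dusp5 (0.57) did not pass without CD HO replicate 2, nor either with the sex term. The null yolk sac values of Efnb2 and Hsd11b2, the null embryo values of Cdh1, Crabp1, Bst2, Ifitm3, Slc38a4 and Rrm2 and the CD yolk sac value of Dio3 were not refitted with libraries left out.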

How the results depend on the processing

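The sex term, the list tests with libraries left out and the fit without yolk sac CD HE replicate 2 were chosen after seeing the data. Leaving out a library leaves a lone sample that is assumed to vary like the other groups. The cause of the changed values was not tested, except that fewer samples or unfiltered genes enter by construction.

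Counts of called genes in embryos moved most in the small comparisons. DESeq2 gave 8 (null HE), 53 (CD HE), 197 (difference) and 385 (WT against WT); no filter gave 43, 695, 949 and 1293. Only the groups compared gave 1486 for CD HO, 31 for null HE, 12 for WT against WT and 1135 shared. The sex term gave 300 for CD HO, 0 for null HE, 2 for the difference, 0 for WT against WT and 276 shared. WT and HE as reference gave 4845 for CD HO. With each library left out the ranges were 3655 to 6298 (null HO), 1272 to 2966 (CD HO), 0 to 1 (null HE), 2 to 849 (CD HE), 3 to 1048 (difference), 2 to 1623 (WT against WT) and 1076 to 2673 (shared). Setd2 in CD embryos ranged from -0.24 to -0.07.

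In yolk sacs DESeq2 gave 1151 (CD HO), 2 (null HE), 7 (CD HE), 13 (difference), 27 (WT against WT) and 691 shared; no filter gave 2055 (null HO), 1662, 46, 164, 122, 294 and 980. Only the groups compared gave 1808 (null HO), 63 (CD HO), 3 (null HE) and 48 shared, and WT and HE as reference 2176 and 1362. The sex term gave 682, 102 and 82 shared. With each library left out the ranges were 165 to 602 (null HO), 66 to 1074 (CD HO), 0 to 1 (null HE), 0 to 7 (CD HE), 1 to 28 (difference), 1 to 12 (WT against WT) and 59 to 449 (shared). Setd2 in null yolk sacs ranged from -0.56 to -0.42.

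The replicate number as a block gave 903 calls for CD HO and 595 shared in yolk sacs and moved no other count by over 1.5 times. Deviations of same-numbered samples correlated at -0.0552 to 0.175 and the labels give no pairing, so the numbers were not taken to pair the samples; a shared factor in yolk sacs is not excluded.

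With an estimated correlation, lists past the threshold went from 10 to 0 (null HO), 8 to 2 (CD HO) and 9 to 0 (difference) in embryos and from 10, 6 and 7 to 0 in yolk sacs; with libraries left out the differences gave 5 to 12 lists in embryos and 2 to 8 in yolk sacs. For HE and WT against WT an estimated correlation took lists from 5 to 2 (null HE), 10 to 0 (CD HE) and 9 to 0 (WT against WT) in embryos and from 11, 9 and 10 to 0 in yolk sacs. With the sex term the adjusted p turned direction for erythroid genes in CD HO embryos (0.0435), cardiac genes in the embryo difference (0.00299) and sex-linked genes in null HO yolk sacs (0.0374). With libraries left out, results that turned direction ranged as follows. In null HO embryos, Prl3d1 ranged from -0.01 to 10.22, and adjusted p from 0.0305 to 0.583 for extraembryonic mesoderm, 2.09e-05 to 0.921 for cardiac and 6.99e-06 to 0.71 for cholesterol genes. It ranged from 0.0301 to 0.881 for extraembryonic mesoderm in CD HO embryos. In the embryo difference it ranged from 0.016 to 0.628 for endothelial, 0.000357 to 0.617 for extraembryonic mesoderm, 5.04e-08 to 0.992 for cardiac and 6.2e-09 to 0.52 for sex-linked genes. In yolk sacs it ranged from 3.7e-08 to 0.677 for erythroid genes in CD HO, and in the difference from 3.62e-26 to 0.258 for erythroid and 0.00413 to 0.951 for integrated stress response genes.

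For the lists of HE and of WT against WT, libraries left out gave 3 to 6 (null HE), 5 to 11 (CD HE) and 4 to 10 lists (WT against WT) in embryos and 7 to 9, 3 to 7 and 9 to 13 in yolk sacs. With the sex term the adjusted p turned direction in null HE embryos for erythroid (3.3e-09), extraembryonic mesoderm (0.323), imprinted (0.0128) and sex-linked genes (0.844), in WT against WT embryos for sex-linked genes (0.592), and in null HE yolk sacs for endothelial (0.157) and sex-linked genes (2.21e-07). The replicate block turned erythroid genes between the WT yolk sacs (0.00422); the endothelial (0.948), Hox (0.343) and proliferation (0.132) lists there and the somite (0.373) and sex-linked (0.142) lists between the WT embryos did not pass with it. Lists that turned with libraries left out ranged from 0.00396 to 0.991 for extraembryonic mesoderm between the WT embryos. In null HE yolk sacs they ranged from 1.51e-08 to 0.628 for endothelial and 7.39e-08 to 0.809 for extraembryonic mesoderm genes, and in CD HE yolk sacs from 1.39e-44 to 0.509 for erythroid and 3.62e-10 to 0.483 for hypoxia genes. Between the WT yolk sacs they ranged from 3.41e-36 to 0.0293 for erythroid and 8.17e-06 to 0.499 for integrated stress response genes.

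Of 215 called embryo genes named, 11 lost the call with DESeq2, 65 with the sex term and 44 in some fit with a library left out; of 129 in yolk sacs, 1, 35 and 79 did. Depth was lower in yolk sacs.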

Other observations

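The tests of zinc finger genes were chosen only after the result was seen.

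Zinc finger genes named Zfp fell often in homozygous embryos. Of 381 tested, 143 were lower in null embryos (37.5%, against 16.1% of other genes; odds ratio 3.14, two-sided Fisher's exact p = 1.58e-23) and 117 in CD embryos (30.7% against 8.71%; odds ratio 4.65, p = 2.1e-33). In yolk sacs 11 and 6 of 377 were lower in the null and CD lines (odds ratios 0.723 and 0.838, two-sided Fisher's exact p = 0.35 and 0.848), and the median change of these genes was -0.07 in both. In simulated yolk sac counts edgeR recovered 11.4% of 1.5-fold changes, so whether these genes fall in that tissue was left open, and the tissues were not tested against each other. An earlier criterion took any odds ratio of 1 or less as evidence against a fall, whatever its p. Genes are not independent replicates in these tests.

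Genes annotated as lncRNA or pseudogene were more often higher than protein-coding genes among the calls. Their share of higher calls was 58.6% against 48.8% in null embryos (odds ratio 1.48, two-sided Fisher's exact p = 9.66e-06), 59.9% against 41.3% in CD embryos (2.13, exact p = 1.11e-09) and 60.5% against 35.8% in null yolk sacs (2.74, exact p = 0.00181). In CD yolk sacs it was 48.1% against 39.8% (1.41, two-sided Fisher's exact p = 0.424), which left open whether the pattern holds there. Gene body length showed no common trend: the median change of genes in the longest of 5 equal bins minus that in the shortest was 0.14 and 0 in null and CD embryos and 0.11 and 0.17 in null and CD yolk sacs.

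Yolk sac CD WT replicate 2 held levels near those of heterozygotes at genes that differ by CD genotype. Rpl29 was 148.7 CPM there and 227.1 in replicate 1, against 116 and 154 in CD HE. Gm8210, named after its values were seen, was 9.49 CPM there and 0.10 in replicate 1, against 9.91 and 6.73 in CD HE. By these genes its genotype label is in doubt, which was not tested. Setd2 was 190.4 CPM in this library and 178.2 in replicate 1. Yolk sac CD HE replicate 2 held transcripts of both sexes, and leaving it out gave 643 calls for CD HO against WT.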
